A study of Metschnikowia pulcherrima with 5 samples.

How the data were processed

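RNA was sequenced in 5 libraries from the yeast Metschnikowia pulcherrima, a biocontrol yeast known for the red iron-binding pigment pulcherrimin. Wild-type cells (wt, n = 2) were compared with the spontaneous mutant W8 (n = 3). Per the labels, W8 carries an early stop codon in snf2 that shortens the predicted protein from 1578 to 420 amino acids. Snf2 is known as the ATPase subunit of the SWI/SNF chromatin remodelling complex. Per the labels' protocols, overnight cultures in potato dextrose broth were diluted to an optical density of 0.4 and grown for 5 to 6 h at 23 °C, cells were broken mechanically, and poly(A) libraries were made with a stranded Illumina kit. Per the labels, all 5 libraries carry the mark noIron in their descriptions, which the sources used here do not explain; no libraries with another mark were analysed here. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

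The deposited table holds CPM values (read counts scaled to library size) for 5570 loci, with 1 column per library and no pooled column. Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2, Salmon and edgeR were used; their versions, roles and order, the genome build, the annotation, the use of strand in counting and the filter on low loci are not given in the sources used here. The deposited CPM columns sum to 1009259 and 1006813 in wt and to 1000709, 953930 and 919976 in W8, so they do not all sum to the same total and had been scaled by the authors to an effective library size that is not the sum of the listed loci. Low values lie on a regular grid: among values below 3 CPM, between 94.4% and 97.9% per library were whole multiples of 1 step within 0.1 of a read. If 1 step is 1 read, the listed loci held 24197958 and 24128885 reads in wt and 25548288, 24124482 and 24884644 reads in W8. The effective library sizes, which the scaling sets and which are not sequencing depth, were 23975959 and 23965614 reads in wt and 25530181, 25289559 and 27049240 reads in W8. Only 11 to 43 loci per library lie within 20 steps of 0, too few to check rebuilt counts, so no count model was fitted. The steps serve to judge depth, to set a level of 3 reads, to size simulated libraries and to compare replicates on estimated reads. The level of 3 reads then corresponds to between 0.111 and 0.125 CPM, and limits based on it cover counting error only.

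Loci are listed by identifiers alone, and neither gene names nor an annotation were used here. Of the 33 gene lists fixed before the data were examined (among them the pulcherrimin genes, SWI/SNF subunits and iron uptake), 0 were tested for that reason, and neither snf2 nor the pulcherrimin genes are reported by name. The rule for named loci, also fixed then, allowed 2 loci that rose and 2 that fell when no names exist. They are those with the largest log2 fold change among loci with adjusted p below 0.05, all W8 values on the same side of both wt values and a mean of at least 5 CPM in the higher group. The 3 listed loci on each side of them were added after their values were seen and are given without identifiers. Near-identical gene copies and overlapping genes could share reads, and that was not checked here.

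For the test, loci with a mean of at least 1 CPM over the 5 libraries (5564 loci; 6 fell below) were put on the log2(CPM + 1) scale and fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with group as the only term and all 5 libraries in the fit. Tests are two-sided with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. A fold change on this scale understates the change of low loci. Where a fold is given as a ratio of mean CPM, this is stated. The fit was tested on simulated libraries with the effective library sizes of this comparison (20 runs on 5570 loci, 200 of them changed). It called 94.5% of loci changed 1.5-fold, 99.6% of those changed 2-fold and 99.1% of those changed 4-fold, and 4.21% of its calls were false. All simulated loci had the same relative spread beyond counting error, the median of the data, and far fewer loci changed than were called here. The simulation thus held no noisier loci, so these rates cannot be read as those of the real calls.

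The letter and number in each identifier were read as the sequence (A to H) and the order along it, the usual build of yeast locus tags; the sources used here do not state this. Adjacent loci means consecutive tested loci of 1 letter. The count of adjacent pairs called in the same direction was set against 10000 random orders (one-sided permutation test, seeded, smallest possible p 0.0001). Shares carry exact (Clopper-Pearson) 95% intervals. Loci are not independent replicates, so these tests describe the placement of calls. Alternatives were other pseudocounts (0.5 and 5 CPM), other filters, 3 other scalings (median of ratios, trimmed mean of M values with trims of 30% and 5%, and quantile), limma without the trend or with robust priors, a replicate term, and leaving out each library.

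The replicate numbers 1 and 2 occur in both groups, but the labels tie them to no shared batch or day, and there are only 2 pairs. They were not treated as pairs.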

Results

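The transcriptomes of wild-type Metschnikowia pulcherrima and of the spontaneous mutant W8 were compared in 5 poly(A) RNA-seq libraries, 2 of wt and 3 of W8. W8 has an early stop codon in snf2 that is predicted to shorten the protein. The comparison asks which transcripts differ between these strains. A spontaneous mutant may carry other changes, so no difference can be assigned to the snf2 stop codon alone. The submitters named the pulcherrimin genes as their interest. Expression was given as CPM for 5570 loci, with an estimated 24124482 to 25548288 reads on the listed loci per library. The median locus lay at 51.9 and 51.2 CPM in wt and between 49.6 and 50.9 CPM in W8. The 50 most abundant loci of each library held 27.6% to 30.3% of the listed CPM.

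Libraries of a group were close to each other and far from the other group. The 2 wt libraries had 12 loci that lay 2-fold or more apart on the log2(CPM + 1) scale. The W8 libraries had 2, 6 and 19 such loci in their 3 pairs. Between a wt and a W8 library there were 347 to 389. The first principal component separated wt from W8 and held 88.9% of the variance, and the second held 6.08%. The replicates were not duplicates of one library: between the wt libraries the mean chi-square per locus (1 degree of freedom, on the estimated reads) was 27.8, and within W8 it was 33.8 to 96.3, where sampling alone would give 1. The median SD between replicates was 0.08 on the log2 scale in wt and 0.12 in W8. An SD from 2 libraries tends to come out lower than one from 3, so these medians are not directly comparable. Per pair of libraries, the median absolute log2 difference was 0.107 in wt and 0.114, 0.135 and 0.164 in W8.

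In W8, 814 loci were higher and 962 were lower than in wt, together 31.9% of the 5564 loci tested (limma, adjusted p below 0.05). The typical change was small. The median absolute log2 fold change of these 1776 loci was 0.54, with a median standard error of 0.11, which is a 1.45-fold change. In 1775 of them every W8 library lay on the same side of both wt libraries. Over all tested loci the groups were separate in this way at 57.3%, where chance alone gives 20%. Under quantile normalization the split turned to 1127 higher and 791 lower loci, so the balance of directions among all calls depends on the scaling. Without wt replicate 1 the count was 912 and without wt replicate 2 it was 1017, because a single wt library was then left and was assumed to vary like the others.

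**Figure D1:**
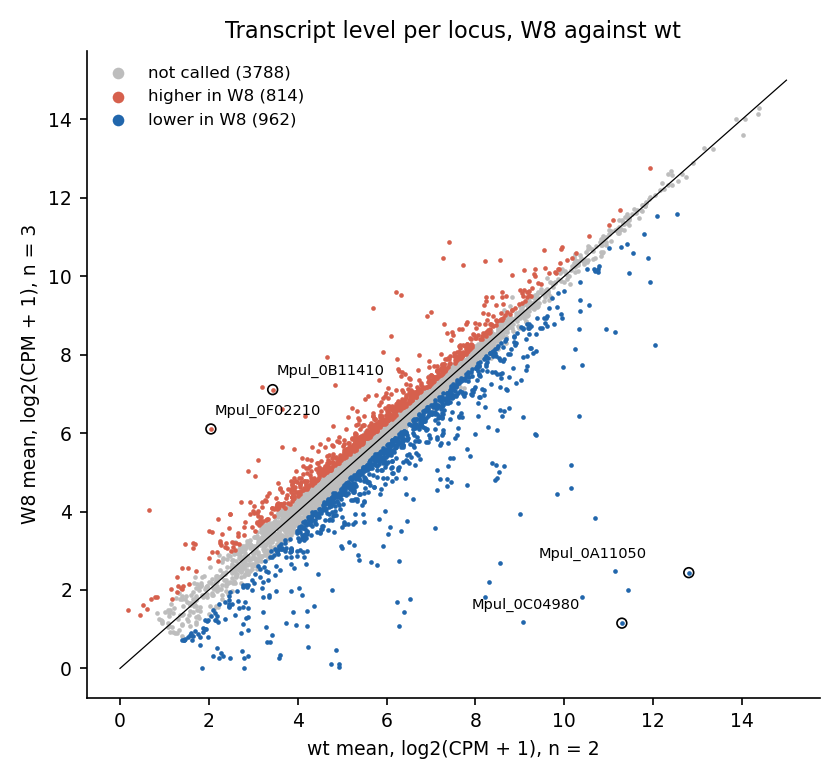
Group mean CPM per tested locus, plotted as log2(mean CPM + 1), in W8 (vertical axis, n = 3) against wt (horizontal axis, n = 2). Loci called higher in W8 are in red (814), called lower in blue (962) and not called in grey (3788), with the line of equal level. Distances from the line can differ from the fitted log2 fold changes, which use means of log2 values. The 4 named loci are ringed, and the strongest changes lie below the line.

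Large changes were mostly falls. Among loci that changed 2-fold or more, 240 were lower and 95 were higher in W8, so that falls made up 71.6% (exact 95% interval 66.5% to 76.4%). At 4-fold or more there were 92 falls and 21 rises, at 8-fold or more 40 and 10, and at 16-fold or more 22 and 1. The 240 loci together held 79125 ± 6671 CPM in wt (SD, n = 2) and 15854 ± 1081 CPM in W8 (SD, n = 3), that is 7.85% and 1.65% of the listed CPM. The 95 loci that rose went from 7793 ± 128 CPM (SD, n = 2) to 25281 ± 1039 CPM (SD, n = 3), or from 0.773% to 2.64%. Of the 240 loci, 162 were lower in wt replicate 2 than in wt replicate 1. Both sets were chosen for their change, so these sums describe its size only.

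**Figure D2:**
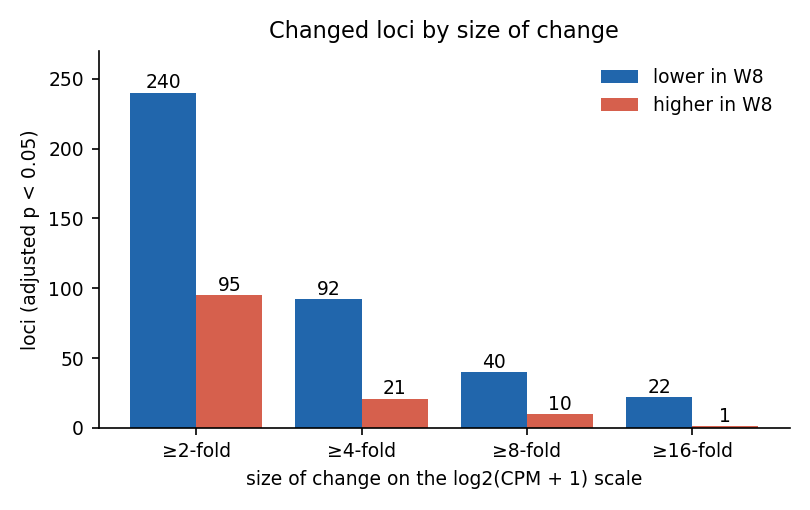
Number of loci with adjusted p below 0.05 (vertical axis) that changed by at least 2, 4, 8 or 16-fold on the log2(CPM + 1) scale (horizontal axis), lower in W8 in blue and higher in W8 in red. Falls outnumber rises in each class, from 240 against 95 to 22 against 1.

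Strong falls included transcripts that were among the most abundant in wt. Of the 100 loci with the highest wt mean, 10 fell 2-fold or more and 4 of these fell 16-fold or more, while 0 rose 2-fold in the limma fit at any p. A ranking by wt favours falls: of the 100 loci with the highest W8 mean, 0 fell and 2 rose 2-fold or more, and of the 100 with the highest mean over all libraries, 5 fell and 0 rose. The 22 loci with falls of 16-fold or more had wt means between 26.0 and 7141 CPM with a median of 444 CPM. Their W8 means had a median of 2.52 CPM, and the median of the level left in W8 was 0.994% of that in wt. They lay on 7 identifier letters but not evenly: 8 of the 22 were on E, which held 603 of the 5564 tested loci. Whether this exceeds a random placement was not tested. Of the 50 loci most abundant over all libraries, with means of at least 2675 CPM, 2 were called higher and 4 lower, and 1 of the 6 changed 2-fold or more. Calls occurred at all levels of expression: in 5 equal classes by mean CPM, from the lowest to the highest, 33.1%, 28.1%, 29.0%, 31.4% and 37.9% were called.

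The largest falls were at Mpul_0A11050 and Mpul_0C04980. Mpul_0A11050 ranked 9 in wt, with 7141 ± 202 CPM (SD, n = 2), and was at 4.43 ± 2.81 CPM (SD, n = 3) in W8. Its log2 fold change was -10.53 with a standard error of 0.37 (limma, adjusted p = 4.06e-09). Mpul_0C04980 ranked 63 in wt, with 2675 and 2351 CPM in the 2 libraries, and was at 1.29, 2.02 and 0.370 CPM in the W8 libraries. Its log2 fold change was -10.21 with a standard error of 0.25 (limma, adjusted p = 1.82e-10), and the ratio of the mean CPM values was 2049. At the levels left in W8 at both loci, carry-over of reads between libraries was not excluded. Over 16 fits, the highest adjusted p (limma) was 0.00224 for Mpul_0A11050 and 3.94e-05 for Mpul_0C04980.

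The fall at Mpul_0C04980 was shared by its neighbours. The next listed locus on one side fell from 907 ± 173 CPM (SD, n = 2) to 20.9 ± 3.80 CPM (SD, n = 3), a log2 fold change of -5.38. The second locus on the other side fell from 1141 ± 38.8 CPM (SD, n = 2) to 23.3 ± 2.45 CPM (SD, n = 3), a log2 fold change of -5.56. The locus between that one and Mpul_0C04980 was much less abundant, at 35.6 CPM in wt and 18.7 CPM in W8, and fell by 0.89 on the log2 scale with a standard error of 0.11 (limma, adjusted p = 0.000149). The second locus on the first side fell from 145 to 114 CPM, a log2 fold change of -0.34. The third locus on the first side, at 219 CPM in wt and 232 CPM in W8, did not pass the test, nor did the third on the other side, at 29.7 and 29.8 CPM. Before that last one, 2 identifier steps have no row and were not analysed here. Around Mpul_0A11050 no neighbour fell to a like degree. The locus before it fell from 29.5 to 17.0 CPM, a log2 fold change of -0.75, and the locus after it rose from 24.6 to 56.5 CPM, a log2 fold change of 1.16 (limma, adjusted p = 9.42e-06).

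The largest rises started from low wt levels. Mpul_0F02210 was at 1.42 and 4.84 CPM in the wt libraries and at 62.8, 51.0 and 89.7 CPM in W8. Its log2 fold change was 4.16 with a standard error of 0.32 (limma, adjusted p = 2.69e-06), and its 3 neighbours on each side had mean levels within 1.80-fold of each other between groups; 1 of them, the second before it, was called lower, from 6.13 to 3.405 CPM (log2 fold change -0.70, limma, adjusted p = 0.0101). Mpul_0B11410 rose from 4.05 and 15.6 CPM in wt to 125, 124 and 163 CPM in W8, with a log2 fold change of 3.90 and a standard error of 0.36 (limma, adjusted p = 1.25e-05). Its called neighbours went both ways. The locus after it rose from 3.63 to 13.1 CPM, while the third after it fell from 21.0 to 4.35 CPM, a log2 fold change of -2.05 (limma, adjusted p = 3.89e-06). The locus before it fell by 0.39 and the second after it by 0.50 on the log2 scale. Because the wt libraries differed, the size of both rises depends on which one is kept. Without wt replicate 1 the log2 fold changes were 3.52 at Mpul_0F02210 and 3.04 at Mpul_0B11410, and without wt replicate 2 they were 4.79 and 4.76. With a pseudocount of 5 CPM they were 3.16 and 3.37.

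**Figure D3:**
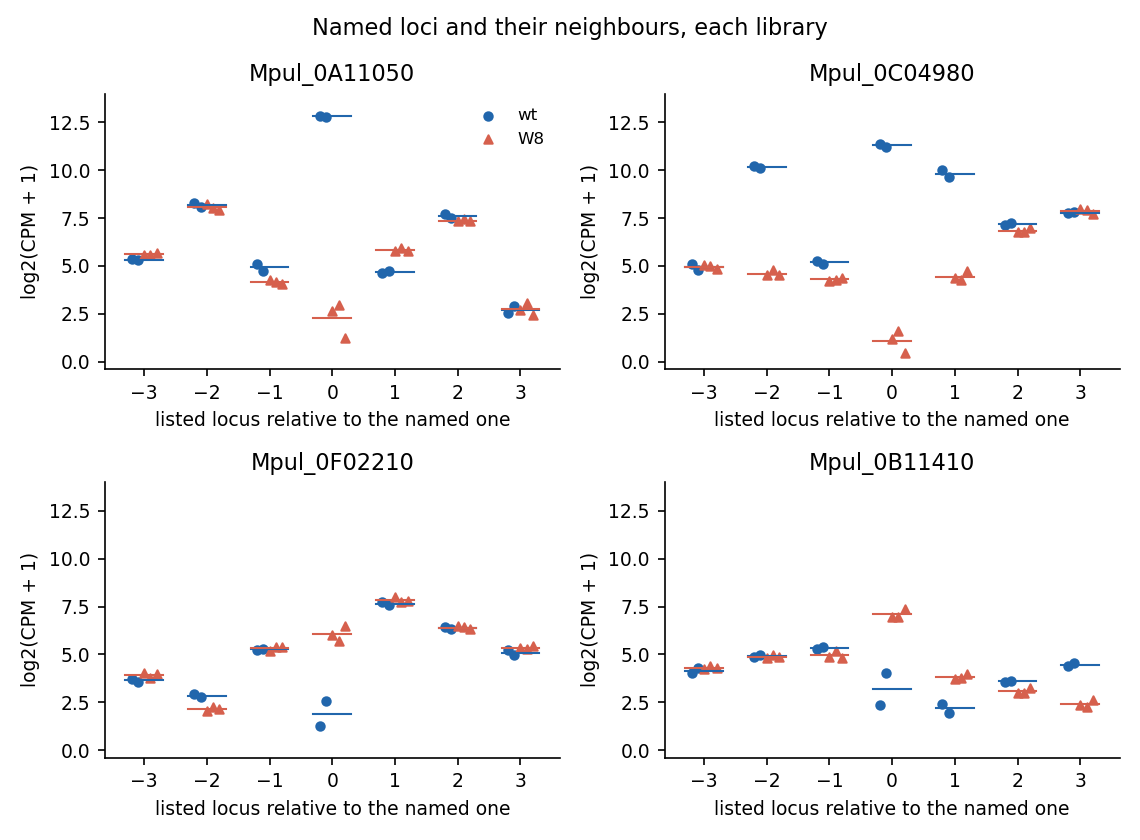
log2(CPM + 1) in each library (vertical axes) at the 4 named loci (position 0) and the 3 listed loci on either side (horizontal axes), with wt as blue circles, W8 as red triangles and short lines at the group means of the log2 values. The positions -2, 0 and 1 around Mpul_0C04980 fall together, while the locus at -1 moves far less.

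Changed loci lay side by side more often than a random order gives. Of 5556 adjacent pairs, 358 had both loci called in the same direction, against 285 in random orders (95% of them between 257 and 313), a ratio of 1.26 (one-sided permutation p = 0.0001, the smallest that 10000 orders can give). For loci that changed 2-fold or more, 29 pairs stood against 11.97 expected, a ratio of 2.42 (permutation p = 0.0001, also the smallest possible). Of these 29 pairs 22 fell and 7 rose. Pairs called in opposite directions did not differ detectably from random orders, with 270 observed and 281 expected (one-sided permutation p = 0.226). The runs were short: the longest run of loci with 2-fold changes in 1 direction was 3 loci, and there were 4 such runs. At a distance of 2 loci the count of 2-fold pairs was 14 against 11.9 expected, within the range of random orders (6 to 19). Over the 11 distances from 2 to 12 loci the counts lay between 6 and 20, and 1 of them, 20 pairs at a distance of 11, was above its range of 6 to 19.

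No identifier letter was shifted as a whole. The median log2 fold change of the 7 letters with more than 1 locus lay between -0.03 on F and 0.01 on B, and the largest difference between 1 letter and the others was 0.03 (permutation p = 0.30). The medians of 5220 windows of 50 consecutive loci stayed between -0.25 and 0.20. The share of called loci varied from 28.8% on B to 36.7% on G (chi-square statistic 20.4, permutation p = 0.0023).

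**Figure D4:**
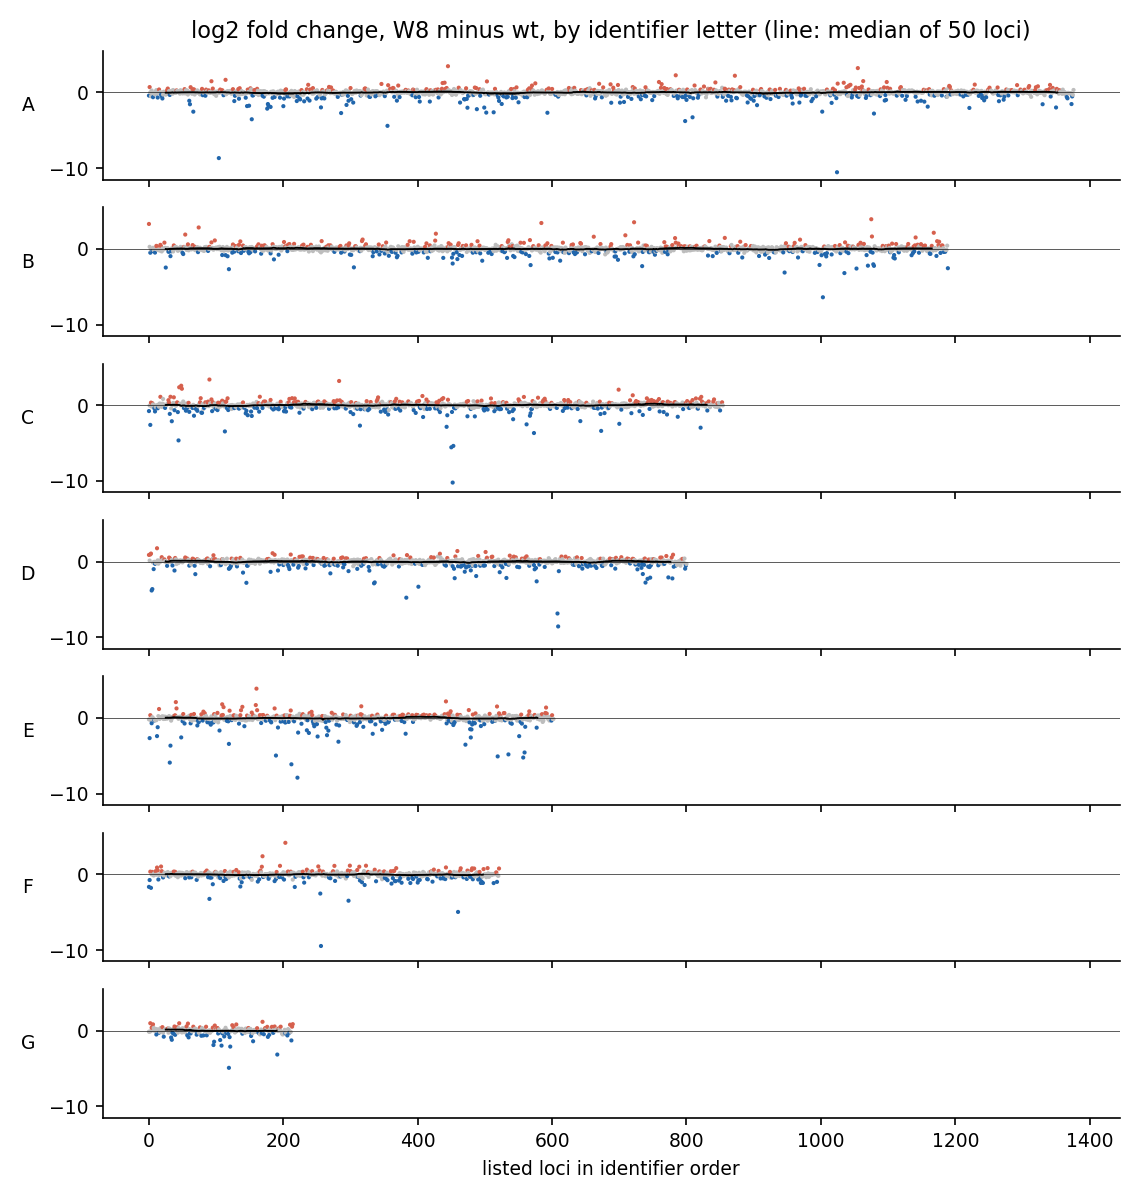
log2 fold change of W8 minus wt (vertical axes, log2(CPM + 1) scale) for tested loci in identifier order (horizontal axis), 1 panel per identifier letter A to G, with loci called higher in red, called lower in blue and not called in grey, and a line for the running median of 50 loci. The line stays between -0.25 and 0.20 in every panel.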

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

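The fits of 2-fold classes under other settings, the restriction to 50 CPM, and the neighbour counts for 2-fold changes and for loci 1 identifier step apart were chosen after seeing the data. Directions held throughout: none of the 1776 called loci changed sign in any of the 15 other fits in which it was tested, and the 4 named loci stayed past the threshold in all of them. Of the 335 loci called with a 2-fold change, between 329 and 335 were called again in each fit except that with a filter at 5 CPM, which tested fewer loci and called 296. Counts depended on the libraries kept and on the settings, and a fit without 1 wt library has a single wt library left. Leaving out 1 library at a time gave 912 to 1887 called loci, with 385 to 844 higher and 527 to 1043 lower; the lowest counts came without wt replicate 1, and 528 loci were higher without W8 replicate 2. Requiring a 2-fold change as well left 335 loci, 95 higher and 240 lower, by construction. With a pseudocount of 5 CPM 61 loci were higher by 2-fold or more, because a larger pseudocount shrinks the changes of low loci. Restricted to loci with a mean of at least 50 CPM, 51 were higher and 116 lower by 2-fold or more, since fewer loci entered. Falls made up 71.6% of the 2-fold calls and at least 62.7% under every other scaling, the lowest with quantile normalization (exact 95% interval 57.3% to 67.8%), which forces all libraries to 1 distribution. At a mean of 50 CPM or more they made up 69.5%, and without 1 library at least 70.7%. The excess of neighbouring calls was 1.17-fold for neighbours within 2 positions and 1.23-fold for loci 1 identifier step apart, both with permutation p = 0.0001. A replicate block gave 2321 called loci against 1776, included 1756 of the 1776 and changed no call of a named locus. W8 replicate 3 has no partner and drops out of that contrast, so the like count without the block is the 1802 loci called without W8 replicate 3. Deviations of same-numbered libraries correlated at 0.25 for number 1 and at -0.00051 for number 2, and wt replicate 2 with W8 replicate 3 at 0.23. Deviations were taken from group means, so those of the 2 wt libraries mirror each other and those of W8 cancel out. The 3 correlations are thus not independent, and the check gives no clear answer on pairing. The alternatives planned for gene lists were not run because no list could be matched to identifiers. Replicates differed on average by more than counting error (mean chi-square per locus of at least 27.8 within a group). Abundant loci can dominate such a mean, so it does not show at how many loci the spread between libraries rather than depth set the precision. Levels near 0.125 CPM rest on about 3 reads.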

Other observations

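The tests of neighbours below were set before their results were seen, and those on lost loci and on the wt replicates were chosen only after the result was seen. No excess of changed loci was detectable near the ends of the identifier series. Among the 25 first and 25 last tested loci of 7 letters, 24 of 350 changed 2-fold or more (6.86%), against 311 of 5213 elsewhere (5.97%), an odds ratio of 1.16 with a 95% interval of 0.721 to 1.79 (Fisher's exact test, two-sided, p = 0.486, adjusted over 4 such tests 0.648). Rises alone were at 2.57% and 1.65% (odds ratio 1.57, 95% interval 0.690 to 3.16, Fisher's exact p = 0.198, adjusted 0.648). The real grouping called 1776 loci, and the highest of the 9 other splits of the 5 libraries into 2 and 3 called 0 (limma; 1 of 10 splits gave as many). Each other split mixes wt and W8 libraries in at least 1 group, so the strain difference adds to its residual spread. Few calls could arise there, and their absence is no separate evidence. At an unadjusted p below 0.05 (limma) the other splits had between 1 and 555 loci, where chance alone gives 278. With 10 splits the share cannot go below 0.1.

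Loci that changed 2-fold or more lay beside each other in 29 pairs. If under 5% of the reads of an abundant locus were counted on its neighbour, the smaller change would stay under 5% of the larger. In 79.3% of the pairs (exact 95% interval 60.3% to 92.0%) the smaller change in CPM was at least 5% of the larger, with a median of 14.9%. This argues against so small a share as the cause for most pairs, but not for the other 6. Overlapping genes or near-identical copies could share a larger part of their reads, which the test cannot decide. A gained or lost segment of 8 or more loci centred on a pair would move the 3 loci on each side as well. Those flanking loci moved in the pair's direction by a median of 0.58 or more in 0 of the 29 pairs (upper limit 11.9%). This argues against segments of that length centred on the pairs. A pair at the end of a segment could escape this test, but the longest run of loci called in 1 direction was 5. Gains or losses of fewer than 8 loci were not tested. The 29 pairs held 54 loci, so some pairs share a locus and both intervals are approximate. Shared promoters or joint control by chromatin remains open as a hypothesis. So do near-identical tandem copies and short gained or lost segments, and none of these was tested.

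A spontaneous mutant can carry other changes than the known stop codon, so each of the 22 loci that fell 16-fold or more may have been lost from the W8 genome rather than silenced. Carry-over of wt reads between libraries was limited to at most 0.0147% to 0.0802% of the wt level, the lowest share left at any locus of 500 CPM or more in wt in each W8 library. At 15 of the 22 loci, the 2 strongly fallen neighbours of Mpul_0C04980 among them, all W8 libraries were above 3 times that share and above 3 reads. This argues against loss at these loci, unless near-identical copies or libraries not analysed here supply the reads. Of these 15, the locus with the least left kept a mean of 0.204% of its wt level and was just above 3 times that share in W8 replicate 2. At 6 loci, Mpul_0A11050 among them, loss and silencing cannot be told apart, since in at least 1 W8 library what is left is within 3 times the carry-over limit or at 3 reads or fewer, and Mpul_0C04980 itself set the limit in all 3 W8 libraries, so the test could not decide on it. None of these 7 lay beside another of the 7, but 1 of them, which fell from 2774 to 3.00 CPM, lay beside a further locus at 9.68 and 2.17 CPM in wt and at 0 in all 3 W8 libraries, so a lost stretch at that place stays open.

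The 2 wt libraries differed at the loci that fell in W8. Of the 40 loci that fell 8-fold or more, 33 were lower in wt replicate 2 than in wt replicate 1, and at the 240 that fell 2-fold or more wt replicate 2 lay nearer to W8 by a median of 9.29% of the distance between the groups (95% interval 6.27% to 12.9%). W8 RNA or cells mixed into that library would shift the loci that rose by the same share. At the 95 loci that rose 2-fold or more the median was -0.402% (95% interval -1.68% to 2.01%), which argues against mixing as the cause over these loci as a set. Of these 95 loci, 46 lay nearer to W8 in wt replicate 2 (48.4%, exact 95% interval 38.0% to 58.9%). The 2 largest rises were among them: Mpul_0F02210 (1.42 and 4.84 CPM in wt replicates 1 and 2) and Mpul_0B11410 (4.05 and 15.6 CPM). A difference in culture state that acts on the loci that fell, such as the spread of harvest times, may remain as a candidate explanation and was not tested.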
